A study of Arabidopsis thaliana with 6 samples.

How the data were processed

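Immunoprecipitated chromatin was sequenced from 6 Arabidopsis thaliana samples in 3 groups of 2: SVP-GFP inflorescences, SVP-GFP seedlings and wild-type inflorescences. Per the labels, all plants grew for 2 weeks in short days with 8 h of light. Plants for inflorescences were then moved to long days with 16 h of light and sampled 2 weeks after bolting. Chromatin was sonicated 6 times for 30 s to fragments of 100 to 500 bp, per the labels. Groups were taken from the sample titles.

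The authors deposited 1 list of mapped reads per group, with the chromosome, position and strand of each read and no header, so the unit is a read position and not a normalised value. The deposited lists hold both replicates of a group together, per the labels, and repeated positions were still present in them. The aligner, the genome build, the read length and any filter are not given in the sources used here, nor whether a reverse read is listed by its leftmost base or its 5′ end, and positions were taken as given. In the SVP-GFP groups the positions run through the 5 chromosomes a second time, which splits each into 2 read lists. The labels do not say whether these are the replicates, so they were used only to see whether a signal recurred. The wild-type list is sorted as a whole and could not be split.

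Coordinates are those of the read lists, counted as given, in their unnamed build. The largest read positions passed the last gene end of the TAIR10.1 annotation by up to 20034 bp. Since no build is named, genes were not assigned to regions, and neither gene lists, motifs, genic location nor the SVP locus were analysed here. The 10 gene lists fixed beforehand were not used. Region-to-gene counts planned for both stages were not run for the same reason.

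At most 1 read was kept per strand and position, and each read was moved 150 bp in its own direction, to the middle of a 300 bp fragment at the centre of the stated range. Reads were counted in 300 bp windows every 50 bp. The expected count was the largest of the scaled control in the window, its density over 5 kb and over 10 kb around it, and the genome mean of the enriched library. The control was scaled by total kept reads. Windows with a Poisson p of at most 1e-05 were merged into regions, each scored by its lowest p, and the summit is the centre of that window. The false discovery rate at a score was the number of regions found with the libraries exchanged over the number found, and regions at or below 0.05 were called. If no score reached that, regions with a Benjamini-Hochberg adjusted p of at most 0.01 and at least 2-fold were used, as happened for inflorescence. These choices, the tests and the rule for named regions were made before the data were examined.

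Inflorescence and seedling were each compared with wild-type inflorescence. Regions were shared when summits lay within 300 bp. This overlap was set against 1000 random placements within chromosomes and against 5 simulated pairs of libraries drawn from the control density smoothed over 10 kb. Since these gave no called region, their regions of highest score at a looser window threshold were used, up to the numbers called in the data. The overlaps were also counted with the wild-type reads dealt at random into 2 parts, a part for each comparison, at the window threshold for seedling. The stages were compared in 300 bp around each summit with a two-sided exact binomial test, the expected share taken from total kept reads, with Benjamini-Hochberg adjustment. A difference passed at an adjusted p of 0.05 and 1.5-fold. Ratios used 0.5 added reads. Where a library had no read, a floor of 3 reads over the pooled library was used in place of the ratio. Intervals are 95% exact Poisson or binomial intervals. Central densities relative to flanks 1 to 2 kb away were counted with reads moved by another distance than in the calls. The central 300 bp there is thus not the called window.

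The rule named the 10 regions with the highest fold in each stage and the 10 with the largest stage difference in each direction among those that passed. The parts of the rule that name genes were not applied. Regions on other grounds, such as the shared ones, were picked for the text after their values were seen.

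Kept reads numbered 1070701 for inflorescence, 3522250 for seedling and 460260 for wild type. At the wild-type depth a window needs 9 reads, 7.77 times the mean, to pass the window threshold. On simulated data with 50 sites per size, the inflorescence procedure found 0% of sites of 2-fold, 6% of 3-fold, 44% of 5-fold and 98% of 10-fold. It called 3 of 77 regions away from a site. The seedling procedure found 2%, 46%, 98% and 100% of the same sizes, with 26 of 148 regions (17.6%) away from a site, above the nominal rate. The stage test found 43 of 200 simulated differences (21.5%) and called 0 others among 5000 regions.

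Alternatives changed the treatment of repeated positions, read shift, window size, control scaling, local background, thresholds, depth, strand support and the overlap distance. Others were added after seeing the data: single read lists, a background from the library's own reads without control, leaving out the chromosome 2 segment, and other region sets for the stage test. The measurement around seedling regions on reads left out of their choice, the overlaps with separate parts of the wild-type reads, the simulated regions of highest score, the comparison of seedling lists at equal depth, the listing of short blocks and the regions compared with them were also added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.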

Results

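SHORT VEGETATIVE PHASE (SVP) is a MADS-domain transcription factor that delays flowering in the vegetative phase and acts later in young flowers. Chromatin bound by an SVP-GFP fusion was immunoprecipitated with an antibody against GFP and sequenced. The fusion was driven by the SVP promoter in svp-41 plants, which lack functional SVP. There were 2 samples of SVP-GFP inflorescences with flowers of stages 1 to 11, 2 of SVP-GFP seedlings grown for 2 weeks in short days, and 2 of wild-type Col inflorescences as a control without the fusion. The reads of both samples of a group were merged, so 3 pooled libraries were compared and no comparison below has a replicate check. Tests on reads therefore compare these libraries, not the conditions, and the intervals cover counting error only.

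The inflorescence library held 2787774 mapped reads at 1070701 distinct positions (38.4%). The seedling library held 5144803 reads at 3522250 positions (68.5%). The wild-type library held the most reads, 6177981, but only 460260 distinct positions (7.45%), so each position was read 13.4 times on average. With 1 read kept per strand and position, the mean 300 bp window held 2.70 inflorescence, 8.87 seedling and 1.16 wild-type reads. The control was thus the shallowest of the 3, and its level at any single region rests on few reads. The SVP-GFP libraries each consisted of 2 consecutive read lists, which the labels do not tie to the replicate samples. The second inflorescence list held 997105 reads at only 88536 positions.

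The first comparison asked where SVP-GFP reads exceeded wild-type reads in inflorescences. Of 188 regions, 115 (61.2%) lay within a single 322 kb segment of chromosome 2 (3187601 to 3509900), and 73 were spread over all 5 chromosomes. The expected level was the larger of the control and the library's own genome mean, and in 28 of the 73 regions outside the segment it was that mean. Over this level the median fold was 4.82 outside the segment and 2.51 inside it. The region of highest fold lay on chromosome 5 (24982551 to 24983500), with 54 reads where 2.70 were expected, 20.04-fold (95% exact Poisson interval 15.1 to 26.1). It was followed by a pair of neighbouring regions on chromosome 4, at 6238801 to 6239700 (14.3-fold, interval 10.5 to 19.1) and at 6236301 to 6238000 (12.5-fold, interval 9.47 to 16.1). In these 3 regions the seedling library stood at 0.338, 1.02 and 0.902 times its genome mean. Their inflorescence reads came from the first read list, with 0, 0 and 1 reads in the second.

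A region on chromosome 2 (8416801 to 8417550) reached 8.66-fold (interval 5.80 to 12.4) and was raised in both inflorescence lists, 11.3 and 13.5 times their means, the latter from 3 reads. It was also raised in the seedling library, at 3.05 times the mean, while the wild-type library had 1 read there. The other 6 of the 10 regions with the highest fold ranged from 5.24-fold on chromosome 3 (17216851 to 17217250) to 5.57-fold. The 5.57-fold value was shared by regions on chromosome 4 (10387901 to 10388250), chromosome 1 (10919451 to 10919800) and chromosome 3 (20258151 to 20258550), with 15 reads each. A region of chromosome 5 (22146551 to 22147000) stood at 5.37-fold. Only 1 of the 10, at 3377801 to 3378800 on chromosome 2 (5.35-fold), belonged to the clustered segment.

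At the 73 regions outside the segment, the central 300 bp held 5.80 times the flanking density in the first inflorescence list and 7.14 times in the second, in part because the regions were chosen on these reads. The seedling lists were raised there by 2.51 and 2.77 times and the wild-type library by 3.26 times (95% exact binomial interval 2.87 to 3.70). The inflorescence count is weakly separated from the control: the exchanged comparison, with wild type as the enriched library, gave 138 regions against 214, and no score reached a false discovery rate of 0.05 (lowest 0.138). Among the called regions the rate rose to 0.643, and it was 0.242 at the regions of 5.57-fold. The 188 regions are those with an adjusted p of at most 0.01 and at least 2-fold, the rule fixed for that case.

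**Figure D1:**
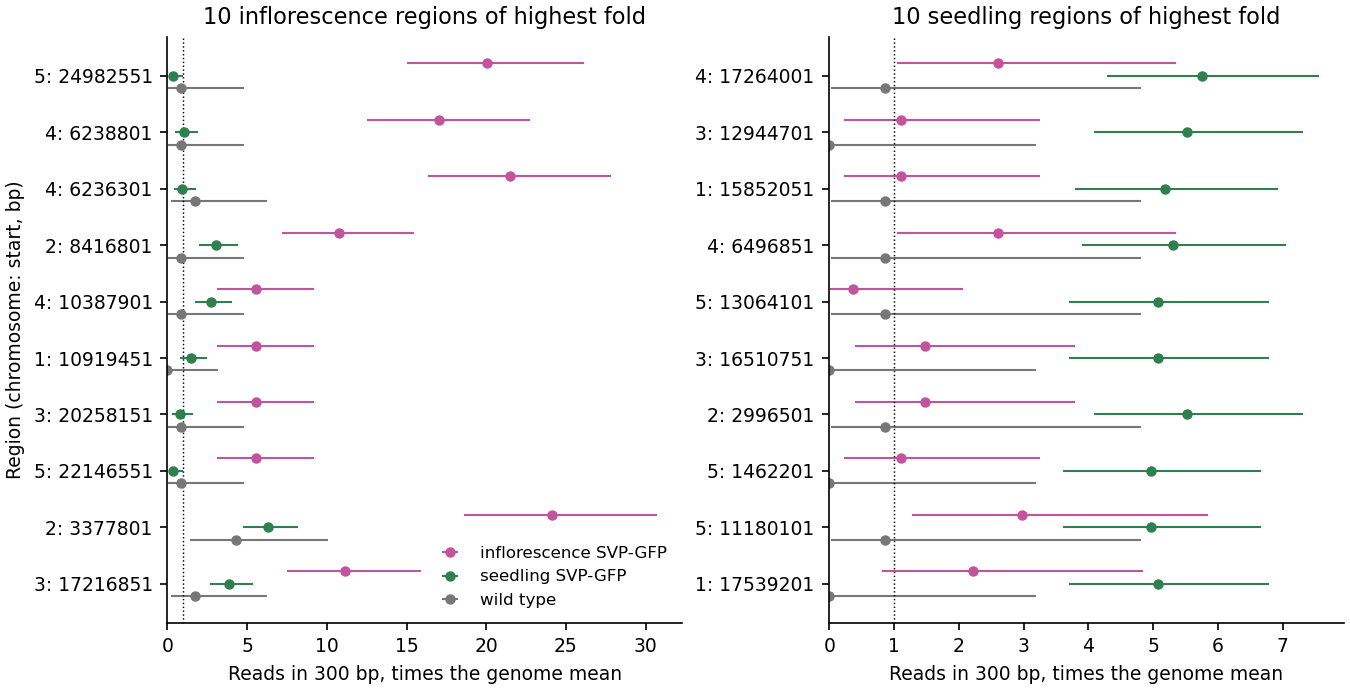
Reads in the 300 bp at the summit of the 10 regions with the highest fold in inflorescence (left) and seedling (right), as multiples of each library's genome mean, for the inflorescence, seedling and wild-type libraries. Bars are 95% exact Poisson intervals; the dotted line marks the genome mean, and the 3 inflorescence regions at the top stand at 17.1 to 21.5 times the mean, far above both other libraries.

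The second comparison set seedling SVP-GFP reads against the same wild-type inflorescence library. Because no seedling wild type was among the samples analysed here, tissue and transgene differ together in it. Seedlings gave 5242 regions, 1.92% of the genome, with a median width of 400 bp and moderate folds (median 2.93, quartiles 2.80 and 3.27). In 2269 of them the expected level was the seedling library's own genome mean rather than a control level, so their folds are not ratios to wild type, and 4945 of the 5242 (94.3%) held at most 1 wild-type read. The highest fold, 5.75 (interval 4.28 to 7.56), lay on chromosome 4 (17264001 to 17264750), with 51 seedling reads where 8.87 were expected. Next came chromosome 3 (12944701 to 12945900) at 5.34-fold and chromosome 1 (15852051 to 15852800) at 5.19-fold. Chromosome 4 (6496851 to 6497450) stood at 5.12-fold, and 2 regions, on chromosome 5 (13064101 to 13064950) and chromosome 3 (16510751 to 16512050), at 5.08-fold. The remaining 4 of the 10 lay between 4.90- and 4.96-fold, on chromosome 2 (2996501 to 2997850), chromosome 5 (1462201 to 1463100 and 11180101 to 11180850) and chromosome 1 (17539201 to 17539900). All 10 were above the genome mean in both seedling lists, by at least 3.13 times, and held 0 or 1 wild-type reads, where the mean window held 1.16 and the choice itself favoured low wild-type counts.

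Across the 5242 regions, both seedling lists were at least 1.5 times their mean in 5119 (97.7%), in part because the regions were chosen on these reads. The seedling regions were denser per megabase on chromosome 2 (48.3) than on chromosome 1 (36.9). Single megabases held from 18 to 130 regions, with a median of 39. Their densest megabase on each chromosome was 16000001 to 17000000 on chromosome 1 (69 regions), 5000001 to 6000000 on chromosome 2 (96), 14000001 to 15000000 on chromosome 3 (101), 3000001 to 4000000 on chromosome 4 (130) and 12000001 to 13000000 on chromosome 5 (111).

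**Figure D2:**
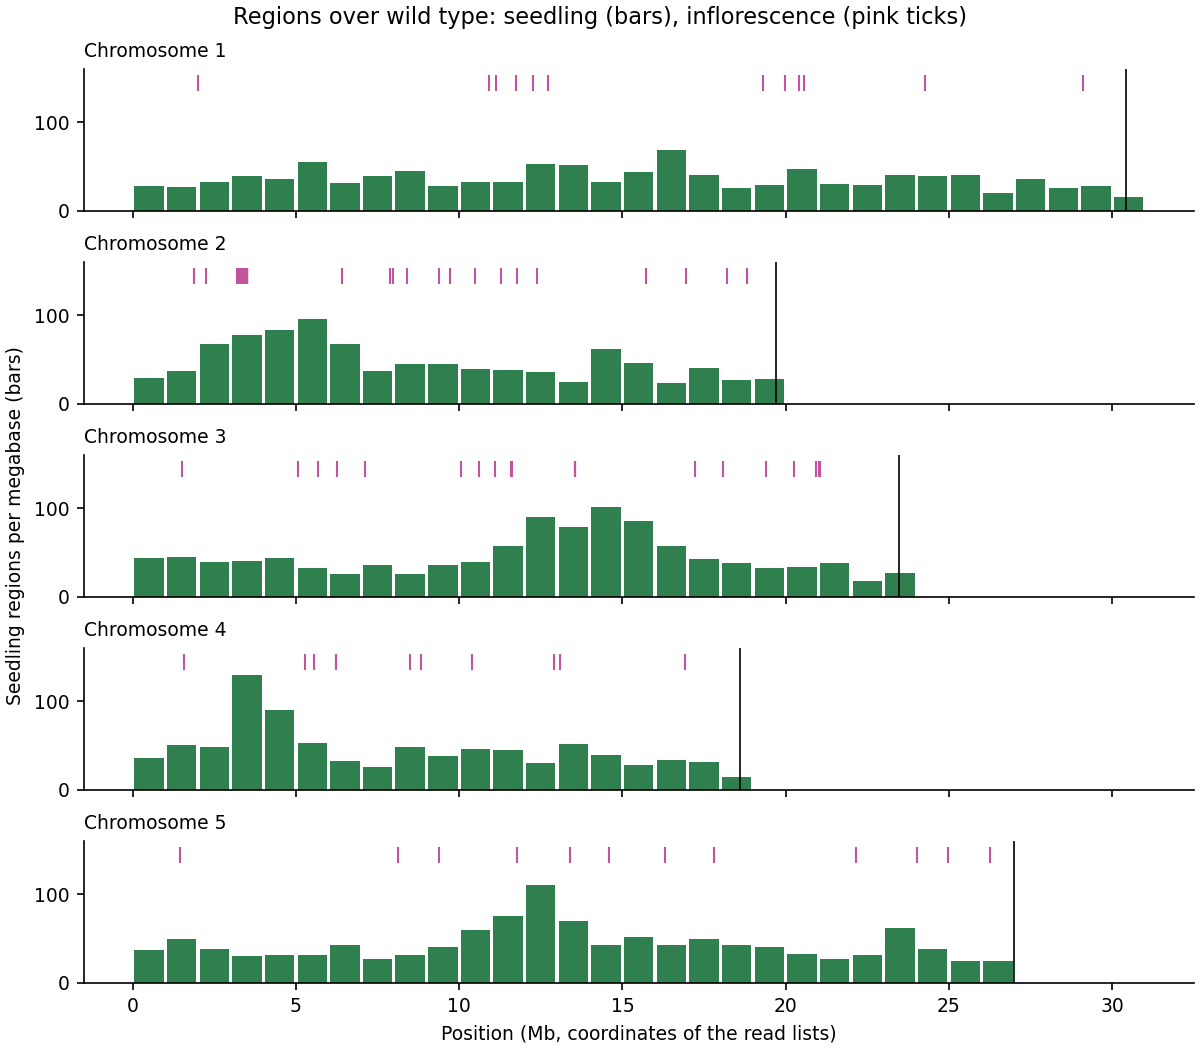
Number of seedling regions in each megabase (bars) and positions of the 188 inflorescence regions (pink ticks) along the 5 chromosomes; the black line is the largest read position, so the last bar of a chromosome covers less than a megabase. Seedling regions peak at 130 in a megabase of chromosome 4, and the inflorescence ticks crowd in 1 segment of chromosome 2.

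The exchanged comparison gave 106 regions, an exchange ratio between 0.0193 and 0.0202 for the seedling list. In simulated seedling libraries 26 of 148 called regions (17.6%) lay away from a site, so the exchange ratio understated the share of false calls there. The count depended on depth, since 0 regions were called with all libraries thinned to 460260 reads, and on the read list, with 2923 regions from the second list alone and 0 from the first. Against the first seedling list, of the same tissue and fusion, the second gave 0 called regions, but 717 to 1221 in 5 draws with the first list thinned to the wild-type depth. A shallower control thus gave more regions there, and the part this plays in the count against wild type was not measured. Around the summits of the called seedling regions, the central 300 bp held 0.795 times the flanking density of wild-type reads (exact binomial interval 0.771 to 0.819). Reads were moved by another distance there than in the calls, so this span is not the called window. In the called windows wild type held 0.608 times its genome mean. In the profile wild type stood at 1.01 times its flanks 75 bp before the summits. It fell to 0.387 and 0.386 times 25 bp before and after them. Such a step can arise where the called windows of the 2 strands overlap under another move. At 275 bp wild type was raised, to 1.48 and 1.56 times. Some calls may thus lie in chance gaps of the wild-type reads, beside places where wild type was raised. How many do was not measured.

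Because regions chosen on a set of reads are high in those reads by selection, the seedling signal was also measured on reads that had no part in the choice. Regions were taken from the first seedling list against a random part of the wild-type reads, which gave 796 regions. Around them the second seedling list held 2.02 times its flanking density (95% exact binomial interval 1.98 to 2.06). The wild-type reads left out of the choice were raised by 1.29 times (1.18 to 1.40) and the first inflorescence list by 1.33 times (1.28 to 1.39). At these 796 regions, inflorescence SVP-GFP and wild-type reads thus had overlapping intervals. Of 878 regions of the first seedling list at the window threshold, 241 (27.4%) had a summit of the second list within 300 bp, against a mean of 13.1 and a highest value of 25 in 1000 random placements. Those lists shared their control. With a separate part of the wild-type reads for each list, 138 of 796 regions (17.3%) had such a summit, against a random mean of 10.8 and a highest value of 22. Separate parts remove only the shared control. Random placement also ignores the uneven density of regions and any read preference that both lists share. The excess over it therefore does not show binding.

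**Figure D3:**
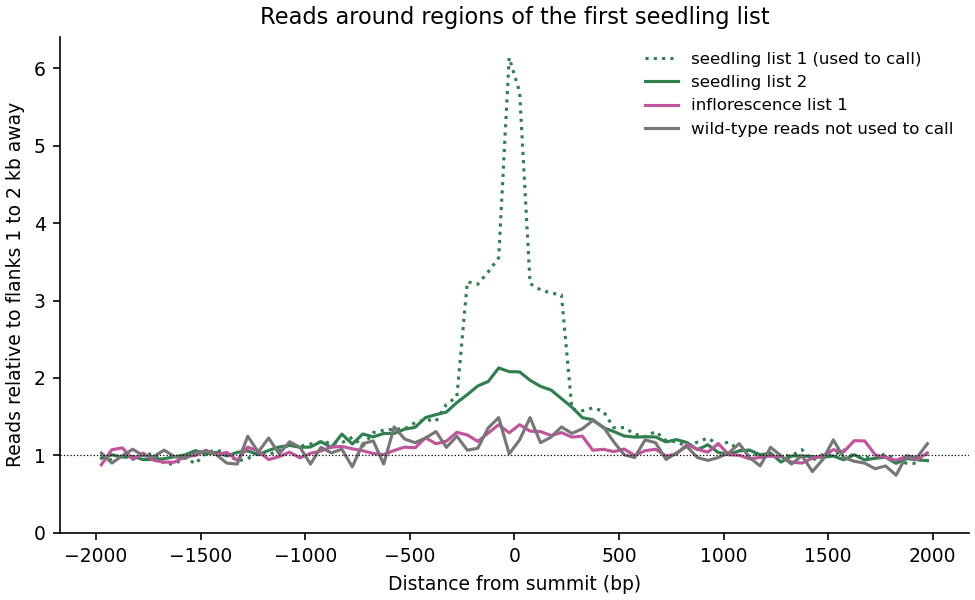
Reads around the summits of 796 regions taken from the first seedling list (dotted green) against a part of the wild-type reads, relative to flanks 1 to 2 kb away, by distance in bp. The second seedling list (green) reaches about 2.02 times its flanks over the central 300 bp, the first inflorescence list (pink) 1.33 and the wild-type reads not used for the choice (grey) 1.29.

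The third comparison asked which regions were common to both stages. Of the 188 inflorescence regions, 12 (6.38%) had a seedling summit within 300 bp. Random placement of the inflorescence regions gave a mean of 5.35 and a highest value of 15 (one-sided permutation p = 0.00699). Outside the chromosome 2 segment, 9 of 73 regions (12.3%) were shared against a random mean of 1.93, with a one-sided permutation p of 0.001, the smallest that 1000 placements can give. The shared region of highest inflorescence fold was the one on chromosome 2 (8416801 to 8417550) with 8.66-fold. Others lay on chromosome 1 (10919451 to 10919800), with 15 inflorescence reads and 13 seedling reads, on chromosome 3 (5677301 to 5677750), with 14 and 17, and on chromosome 5 (14600101 to 14600400), with 13 and 30. Wild type had 0 reads in the last 3, where the mean window held 1.16 and the choice in both stages favoured low wild-type counts. Random placement leaves out the control that both stages share. It also sets each region independently and evenly along its chromosome. It thus ignores the crowding of 115 of the 188 regions in the segment and the uneven density of seedling regions. Both permutation p can therefore be too low. Simulated libraries without any site gave no called region. Their 188 inflorescence and 4327 to 4576 seedling regions of highest score, taken at a looser window threshold, shared a mean of 9 regions (5 to 14 in 5 draws). That range includes the observed 12, but the draws followed a smoothed control. Of the 188 observed regions, 115 crowded in the segment, so the observed and simulated overlaps are not fully alike. With a separate part of the wild-type reads for each stage, 9 of 194 inflorescence regions were shared (random mean 5.15, highest 17), and 4 of 70 outside the segment (random mean 1.78, highest 7). With separate parts the overlap was thus not separated from chance, over all regions or outside the segment. Outside the segment only that count bears on the shared control, since the simulated overlap covered all 188 regions.

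The fourth comparison set the inflorescence and seedling SVP-GFP reads directly against each other at the 5418 regions of either stage. The region on chromosome 5 (24982551 to 24983500) differed most, with 54 inflorescence and 3 seedling reads, a log2 ratio of 5.68 (95% exact binomial interval 4.26 to 8.21, adjusted p = 8.56e-28). The pair of regions on chromosome 4 followed, at 6236301 to 6238000 (log2 ratio 4.50, interval 3.50 to 5.85) and 6238801 to 6239700 (4.01, interval 3.02 to 5.29). A region on chromosome 2 (16951901 to 16952200) had 14 inflorescence and 2 seedling reads, a log2 ratio of 4.25 (interval 2.40 to 7.71). All of these regions had been chosen for high inflorescence counts and were tested on the same reads, so their ratios and intervals tend to lie too high and their p too low. On the seedling side, the 10 regions ranked highest by the ratio with 0.5 added reads had no inflorescence read, so their ratios are bounds. These included chromosome 1 (9138751 to 9140250) and chromosome 2 (5891801 to 5892250), each with 43 seedling reads, at least 4.36-fold higher in seedling against a floor of 3 inflorescence reads. The upper end of their exact binomial interval was a log2 ratio of -1.76, a weaker bound. The mean window held only 2.70 inflorescence reads, so some windows are empty by chance. Of the 5242 seedling regions, 174 held no inflorescence read. Over all 5242, inflorescence stood at 1.29 times its genome mean on average.

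In all, 1300 regions passed an adjusted p of 0.05 and a 1.5-fold change in the two-sided exact binomial test with Benjamini-Hochberg adjustment, 175 higher in inflorescence and 1125 higher in seedling. Of the 175, 115 lay in the chromosome 2 segment. The split depended on the scaling. Most of the regions had been chosen on seedling reads, and their median log2 ratio was -1.30. With the libraries scaled to that median ratio, 190 regions were higher in inflorescence and 0 in seedling. The 10 regions named on the inflorescence side passed under both scalings, and the 10 on the seedling side lost the call with the median ratio. Among 1063 regions chosen with the first seedling list or in inflorescence and tested with the reads of the second list, 177 were higher in inflorescence and 60 in seedling. The inflorescence regions were still tested there on the reads that chose them, so these counts are not alike.

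**Figure D4:**
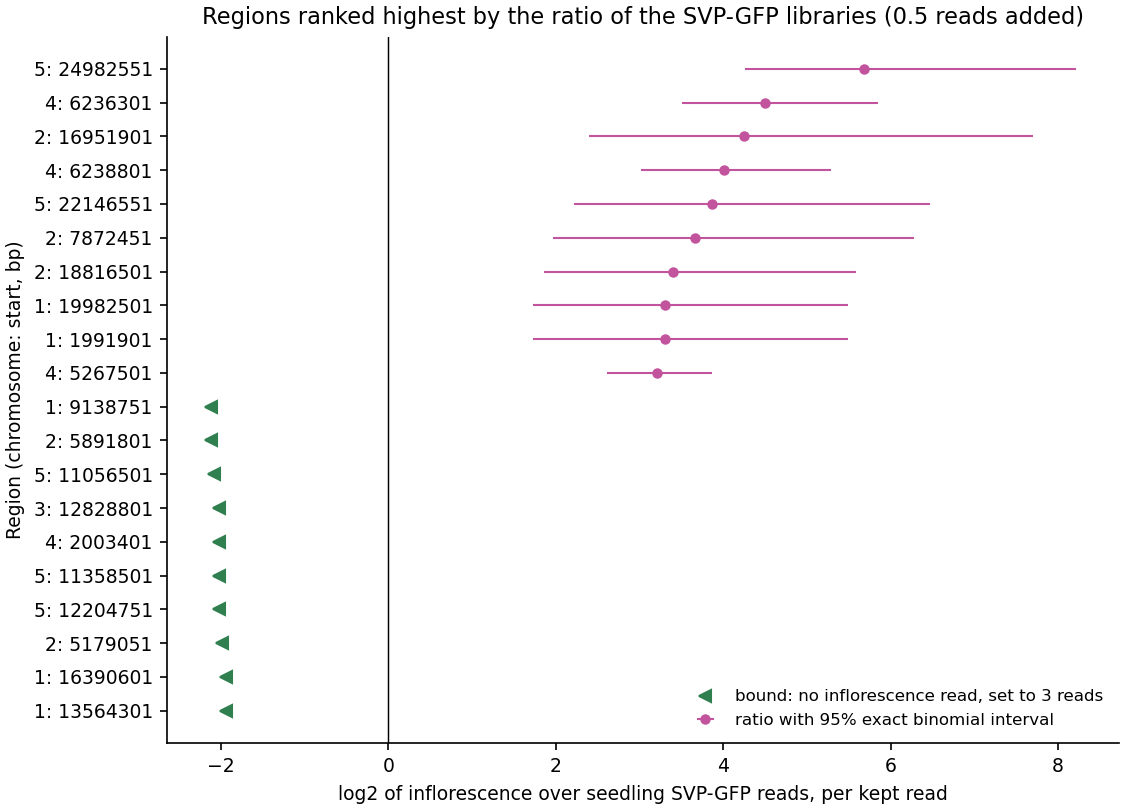
log2 ratio of inflorescence over seedling SVP-GFP reads per kept read for the 10 regions ranked highest on each side by the ratio with 0.5 added reads, labelled by chromosome and start. Points carry 95% exact binomial intervals, and triangles are bounds for regions without an inflorescence read, which was set to 3 reads; values run from 5.68 on chromosome 5 to -2.12 on chromosomes 1 and 2.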

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

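The tests of the short blocks, and of seedling summits found without the control, were chosen only after the result was seen, and the test on left-out wild-type reads was added once the latter was known, as was the list comparison at equal depth.

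The 20 regions ranked highest by their ratio between the SVP-GFP libraries, with 0.5 added reads, drew attention because the exact binomial test found a difference between inflorescence and seedling. On the inflorescence side the log2 ratios were 5.68 on chromosome 5 (24982551), 4.50 and 4.01 on chromosome 4 (6236301 and 6238801), and 4.25 on chromosome 2 (16951901). They were 3.86 on chromosome 5 (22146551), 3.67 and 3.41 on chromosome 2 (7872451 and 18816501), 3.30 at each of 2 regions of chromosome 1 (19982501 and 1991901) and 3.21 on chromosome 4 (5267501). In the last region wild-type inflorescence also stood high, with 16 reads or 13.8 times the mean, against 3.50 times in seedling, and all 20 regions were tested on the reads that chose them. On the seedling side none of the 10 regions had an inflorescence read, so the values are bounds against a floor of 3 reads and do not show that order. They were -2.12 on chromosome 1 (9138751) and chromosome 2 (5891801), -2.09 on chromosome 5 (11056501) and -2.02 at 4 regions, on chromosome 3 (12828801), chromosome 4 (2003401) and chromosome 5 (11358501 and 12204751). The last 3 were -1.98 on chromosome 2 (5179051) and -1.95 at each of 2 regions of chromosome 1 (16390601 and 13564301).

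Short blocks of reads formed the first pattern: 10 stretches stood at least 10-fold above the expected level in either direction of a comparison with wild type, 7 highest in wild type and 3 in inflorescence. The 7 were listed for being higher in wild type, so their number does not bear on binding of SVP-GFP. On chromosome 1 (25986251 to 25987800) 133 wild-type reads were 115 times the mean, against 19.1 in seedling and 2.23 in inflorescence. Wild-type blocks of chromosome 2 at 3624251 and 9586401 were also raised in seedling, at 31.9 and 10.4 times the mean. In the rest of the 7 seedling stood at 0.113 to 2.93 times. At the 3 inflorescence blocks, which include a neighbouring pair, the second list held 1 read where the first predicted 14.1, or 7.08% (0.178 to 40.1). At 48 other regions chosen on the first list it held 91.7% (77.3 to 108). This argues against a signal at the blocks shared by both lists. It does not decide on binding of SVP-GFP in the first list alone. Wild type was also raised at the inflorescence regions outside the segment, so the 91.7% can be recurring background. It does not show that the second list would carry bound sites. Cloned DNA or cDNA in 1 or more libraries remains a candidate explanation, since the offset between strands lay on either side of the bound of 50 bp. Its median size was 67.1 bp (26.2 to 86.2 over blocks), which counts reversed offsets as if positive. The signed median was 37.8 bp (quartiles -5.98 and 68.1). At the 3 inflorescence blocks the signed offsets were -86.2, 1.37 and -8.43 bp. The 500 seedling regions of highest score had a signed median of 64.0 bp (quartiles 32.2 and 88.1). All offsets were taken on unmoved positions, in regions chosen on reads moved by 150 bp. That choice itself favours forward reads before the summit and reverse reads after it. The 64.0 bp is thus no measure of bound sites, and the offsets of the blocks are pushed the same way. If reverse reads are listed by their leftmost base, every signed offset grows by the unknown read length. The blocks include the 3 inflorescence regions of highest fold, which are also among the stage differences above.

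The seedling regions formed the second pattern, and a read preference of chromatin also present in wild type was not the whole cause at 796 regions called against a part of the wild-type reads, a choice that itself passes over places high in wild type, since left-out wild-type reads showed 28.1% (17.7 to 39.3) of the seedling excess. At 593 summits found in the first list without any control, however, the wild-type excess was 116% of that of the second list, so those summits may largely mark such a preference. Variation between 2 read lists of the same group cannot be told apart: at the window threshold the second list gave 22.8% (21.1 to 24.6) as many regions against the first list as against wild type, below the bound of 25%, but that bound took no account of depth, and with the first list thinned to the wild-type depth the share was 37.6 to 41.8% in 5 draws. A difference in depth cannot be told apart from a loss of power, because 0 regions remained at equal depth where a window needs 7.77-fold and the median fold was 2.93. At that depth 103 seedling regions passed the window threshold, against 130 with the libraries exchanged. Seedling tissue stays open as untested, since the second list also gave 4931 regions (183 exchanged) against the first inflorescence SVP-GFP list, which is deeper than wild type and of the same tissue.

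The chromosome 2 segment formed the third pattern, with 115 inflorescence regions within 322 kb. Outside the called regions, inflorescence reads stood at 7.62 times the genome mean, wild type at 5.15 and seedling at 3.55. The inflorescence to wild-type ratio there was 1.48 times the genome median (1.42 to 1.55), an interval that spans the bound of 1.5 set beforehand. That interval lies above the genome median, although removing the called regions lowers the ratio by construction. The segment thus also gained reads outside the called regions. Over the whole segment the ratio was 2.19 (2.14 to 2.24). Whether the called regions hold separate bound sites on top of this wider gain cannot be told from these values. The nuclear chromosome 2 carries a large insertion of mitochondrial DNA, and organelle reads placed there might raise all 3 libraries, which was not tested.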

How the results depend on the processing

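Single-list, own-background, excluded-segment, split-control and changed-region-set alternatives, and the inflorescence rate of 0.05 without the second rule, were chosen only after the result was seen. No paired analysis was possible because the replicates of a group are merged and carry no label, so leaving out a replicate, a replicate block and a split by lane were not run, nor was any planned gene, motif or gene-list alternative. Strand-lag shift and median-ratio scaling kept all 3 region counts within 1.5 times the main values. The strand-lag shift lowered the log2 folds of the 3 highest inflorescence regions from 4.32, 3.84 and 3.64 to 2.89, 2.37 and 2.54. Of the 10 named inflorescence regions only that of chromosome 4 at 10387901 rose, from 2.48 to 2.66. Every read kept gave 18774 inflorescence, 0 seedling and 0 shared regions and 4220 stage differences, 290 higher in inflorescence and 3930 in seedling. At most 2 reads per position gave 777 inflorescence and 53 shared regions. Windows of 200 bp gave 3205 seedling and 5 shared regions, and windows of 500 bp 122 inflorescence regions. Without the 5 and 10 kb background there were 9557 seedling and 56 shared regions. Support on both strands left 6 shared regions. An exchange rate of 0.01 gave 0 inflorescence, 0 seedling and 0 shared regions, a rate of 0.10 gave 0 inflorescence and 0 shared regions, and a rate of 0.05 gave 0 inflorescence regions. Thinning to equal depth gave 0 seedling and 0 shared regions and 49 stage differences, 49 higher in inflorescence and 0 in seedling. The first seedling list alone gave 0 regions and the second 2923. The library's own background gave 115 inflorescence and 77 shared regions. Leaving out the segment left 73 inflorescence regions, by construction. Stage differences numbered 190 with median-ratio scaling (0 higher in seedling) and 2279 after subtracting the control (2098 higher in seedling). They numbered 755 with the first inflorescence list (585 higher in seedling), 237 with regions of the first seedling list and reads of the second (60 higher in seedling), and 182 at inflorescence regions alone (0 higher in seedling). For inflorescence the exchange rates were applied without the second rule, so rate and rule changed together there. Stricter rates, thinner SVP-GFP libraries and fewer regions shrink counts by construction, and for the other changes the cause was not tested. No named region changed direction under the alternatives run on it. At equal depth 8 of the 10 named seedling and 4 of the 10 inflorescence regions fell short of the window threshold, and 6 of the 10 stage differences named on the inflorescence side and 10 on the seedling side lost their call. Of the named inflorescence regions, 4 fell short with 200 bp windows, 3 with 500 bp windows, 3 with the strand-lag shift and 1 with every read kept, and 1 named seedling region did with the strand-lag shift. In simulated inflorescence libraries 6% of 3-fold sites were found, and 46% in simulated seedling libraries, so sites of that size can be missed at these depths.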

Other observations

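The megabase counts, the calls from the libraries' own background and the comparisons of read lists were chosen only after the result was seen.

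The densest 11 of 116 full megabases held 1020 seedling regions, 19.9% of those in full megabases, where the median megabase held 39. Kept reads there stood at 1.52 times the genome mean in seedling and 1.46 times in wild type. Both values lean on 1 of the 11, the megabase of chromosome 2 that holds the clustered segment, with 83522 seedling and 13019 wild-type reads. In the densest megabase of chromosome 4 (3000001 to 4000000) the seedling reads were 1.64 and the wild-type reads 1.37 times the mean. In that of chromosome 1 (16000001 to 17000000) the values were 1.07 and 1.04.

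Regions called from each library alone, without a control, numbered 3707 in seedling, 115 in inflorescence and 78 in wild type. Of the 115 in inflorescence, 77 had a seedling region within 300 bp and 55 a wild-type region. Of the 3707 in seedling, 51 had a wild-type region. That number is limited by the 78 in wild type, whose library held 460260 kept reads against 3522250 in seedling.

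Across 10 kb bins, the kept reads of the seedling lists had a Pearson correlation of 0.921 with each other and those of the inflorescence lists 0.855. Spearman correlations across the same bins were 0.876 and 0.272. The second inflorescence list reached a Pearson correlation of 0.7997 with wild type, where the Spearman correlation was 0.148. Bins are not independent replicates, and no test was made on these values.

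Read repetition differed between lists of the same group. In inflorescence, 55.0% of reads were at distinct positions in the first list and 8.88% in the second. In seedling these shares were 51.6% and 79.9%. The strand lag with the most matching positions was 85 bp in inflorescence, 95 bp in seedling and 118 bp in wild type, each short by a read length if reverse reads are listed by their leftmost base.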
